A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

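RNA of 12 yeast cultures, 4 each of WT, pup2-ts and rpn5-ts, was measured as sequencing counts. The deposited table gave raw counts per annotated feature, and its 12 columns were matched to the samples by the names in the labels. Per the labels, RNA was extracted with hot acid phenol and treated with DNAse, and libraries of polyadenylated RNA were made with a KAPA mRNA HyperPrep kit. Per the submitters' processing notes, STAR 2.5.2b and featureCounts of Subread 1.5.1 were used with the build sacCer3. Those notes do not say how reads with several places in the genome were handled. Genes with near-identical copies (ribosomal protein, histone, HXT, TEF and HSP paralogs, and YHL050C) therefore share reads to an unknown degree.

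Of 12768 features, 5585 were matched by locus tag to protein-coding genes of the R64 gene table, which holds 6021, and other features were left out of the comparisons. For 92.1% of them the interval in the table contained the R64 coding interval, and 385 overlapped another gene on the same strand. Counting was stranded by its values: annotated units nested in a gene on the other strand held 3.23% of the gene's read density, and those on the same strand 104.34%. Totals ranged from 18.5 to 60.6 in genes and from 21.5 to 70.1 in all features, in units of 1e6 counts. No pair of replicates was a copy of another by a chi-square test of their counts.

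Counts were analysed with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors), which left 5560 genes. The 3 groups were fitted together and compared by the robust quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjusted p under 0.05. The same fit was tested against a fold of 1.5 with glmTreat. The standard error was taken as the log2 fold change over the square root of F. Of 37 gene lists fixed, 35 were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with strain markers left out, and p adjusted over the 35 lists of a comparison. With an estimated correlation, both proteasome particles, the assembly factors and pyrimidine synthesis held in pup2-ts against WT. In rpn5-ts against WT the same lists held along with the iron regulon, M/G1 genes and the pheromone response, and in rpn5-ts against pup2-ts M/G1 genes held. The lists of strain markers and of mitochondrially encoded genes were not tested, the latter because 0 of its 8 members were in the table.

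The tests, lists, named genes and first set of alternatives were chosen before the data were examined. Named genes were PUP2, RPN5, RPN4 and the strain markers, and, outside the markers, the 8 largest rises and 8 largest falls of each comparison with WT (6 and 6 between the mutants). These had to pass the threshold, reach 10 CPM in a group and have groups that did not overlap. Up to 4 members with the lowest adjusted p were taken from each list described. Alternatives were relative log expression and upper-quartile factors, DESeq2 1.42.0, limma-voom, no filter, a filter at 10 CPM in 4 libraries, the replicate number as a block, the form of the name as a factor, replicates of 1 form alone, the 8 libraries of a comparison alone, each library left out in turn and an estimated correlation. Agreement of the mutants was set beside simulated unchanged groups (seed 1), split WT libraries, the filter at 10 CPM and genes outside the lists. Alternatives added after the data were seen were the block without WT replicate 1 or without the library labelled rpn5-ts replicate 1, that library left out of every comparison, all annotated features, the block with an estimated correlation, and the block and left-out libraries for the agreement.

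Whether replicate numbers pair the libraries was checked on their deviations from the group means. The 12 correlations between libraries of the same number in different groups ranged from 0.14 to 0.78, all above the bound set for pairing. Blocked counts of genes are therefore given beside the unblocked ones. Lists and their members are given without the block unless it is named. The same-numbered library was the closest for 6 of 12. For the others it was the other library of the same form of the name. The correlations therefore do not tell a pairing by number from the form.

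The test was tried on simulated data for pup2-ts against WT, with 200 of 5559 genes changed, 50 at each fold. It recovered 22% at 1.5-fold, 74% at 2-fold, 96% at 3-fold and 100% at 4-fold, with 11 false calls (7% of calls) and 0 calls in the other comparison. A list changed by 1.5-fold was recovered, and 0 others of 35 were called. Simulated genes varied independently and held no difference between forms of the name. The simulation therefore cannot show how often lists are called falsely in the real libraries. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.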

Results

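Polyadenylated RNA of budding yeast (Saccharomyces cerevisiae) was sequenced in 12 libraries that fell into 3 groups of 4, described by the series as biological replicates. WT cells were set beside cells carrying temperature-sensitive (ts) alleles of PUP2 or RPN5. Pup2 is an alpha subunit of the core particle of the proteasome, the barrel in which ubiquitinated proteins are degraded, and Rpn5 is a subunit of the lid of its regulatory particle. Cells grew in rich medium (YPD) to an optical density of about 0.5 without further treatment, and the labels used here state no growth temperature. Counts in protein-coding genes, in units of 1e6, totalled 30.2, 27.7, 23.9 and 60.6 in WT replicates 1 to 4. The pup2-ts libraries held 28.2, 25.4, 30.4 and 22.7 and the rpn5-ts libraries 32.6, 18.5, 22.7 and 19.0. Protein-coding genes took 86.44% of all counts and units annotated as antisense 10.15%. Those units include ones that overlap a gene on their own strand, so the share does not measure antisense RNA. The tested non-coding units without a gene on their own strand held 1.44% to 2.89% of gene counts. Expression levels are CPM (counts in a library of 1e6) scaled by TMM factors, given as mean ± SD of 4 libraries, and log2 fold changes carry their standard error (SE).

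Libraries differed by strain and by a second property that the group labels do not give. The names of replicates 3 and 4 hold the word DNAse and those of replicates 1 and 2 do not, in all 3 groups. Between these forms of name, with group as a term, 3511 of 5560 genes differed, 1623 higher and 1888 lower in replicates 3 and 4. Glycolysis genes were higher in replicates 3 and 4, with 16 of 16 members called and a median log2 difference of 1.33. Genes of the tricarboxylic acid cycle were higher too, with 14 of 15 called and a median of 0.81. Their adjusted p was 1.2e-06 for glycolysis and 4.9e-07 for the cycle, against adjusted p = 0.98 and adjusted p = 0.20 with an estimated correlation. The 10 most abundant genes took 5.1% to 8.4% of gene counts in replicates 1 and 2 and 11.1% to 13.1% in replicates 3 and 4. For lists called against WT, medians within each form are given beside the pooled ones.

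**Figure D1:**
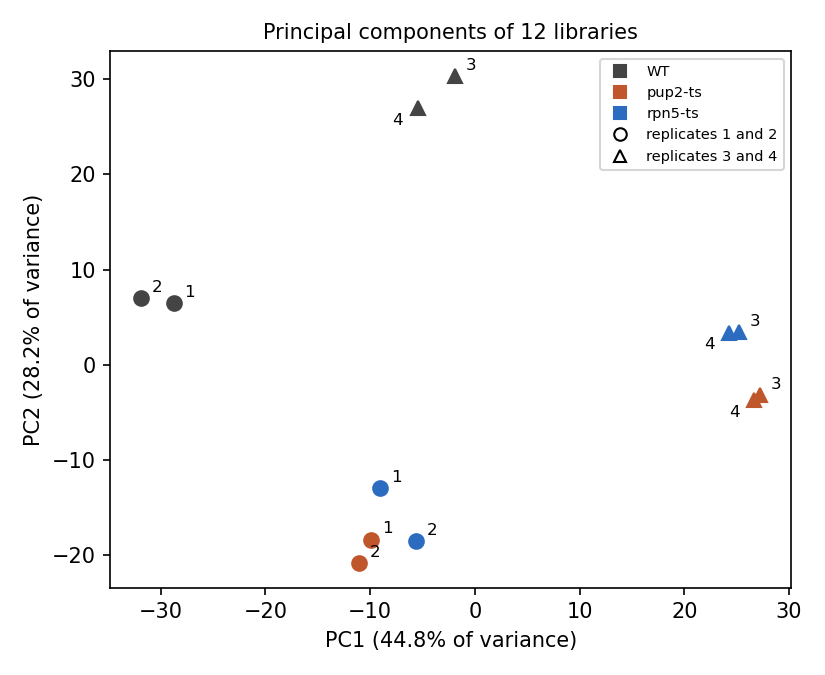
Principal components of log2 CPM in the 12 libraries, one point per library, with the share of variance on each axis (44.8% and 28.2%), colour for the group and shape for the form of the name (circles replicates 1 and 2, triangles replicates 3 and 4). Replicates 3 and 4 of both mutants lie at 24.3 to 27.2 on the first axis, replicates 1 and 2 of the mutants at -11.0 to -5.6, and WT at -31.8 to -1.9.

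Transcripts of the altered genes and of the strain markers were read in every library first. PUP2 (YGR253C, chromosome VII, 998301 to 999187) measured 195 ± 16.6 CPM in WT, 251 ± 20.9 in pup2-ts and 426 ± 57.9 in rpn5-ts. RPN5 (YDL147W, chromosome IV, 190873 to 192407) measured 348 ± 81.1 CPM in WT, 743 ± 89.3 in pup2-ts and 512 ± 156 in rpn5-ts. Gene counts do not show the sequence of an allele, so the labels were checked on the markers. The labels give both mutants URA3, LEU2 and HIS3 present, CAN1 replaced and LYS2 deleted, all unlike WT. The labels also give all strains a deletion of MET17 (met15 in the labels). LEU2 was not in the count table and could not be checked. URA3, an enzyme of uracil synthesis, stood at 4.09 ± 0.49 CPM in WT, 107 ± 12.6 in pup2-ts and 106 ± 19.0 in rpn5-ts. CAN1, the arginine permease, stood at 194 ± 20.9 CPM in WT, 13.1 ± 2.47 in pup2-ts and 14.5 ± 1.85 in rpn5-ts. URA3 shares 75 bases with TIM9 on the same strand, so its level is uncertain by that much. HIS3 ranged from 36.5 to 77.6 CPM in WT and from 67.4 to 118 in the mutants.

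LYS2 and MET17 did not follow the labels throughout. LYS2, an enzyme of lysine synthesis, ranged from 120 to 207 CPM in WT and reached at most 0.209 in pup2-ts and 0.181 in rpn5-ts replicates 2 to 4, but stood at 213 in the library labelled rpn5-ts replicate 1. MET17, an enzyme of methionine and cysteine synthesis, ranged from 196 to 587 CPM in the 4 libraries labelled pup2-ts and stood at 249 in the library labelled rpn5-ts replicate 1. It reached at most 0.0931 in WT and 0.0906 in the other rpn5-ts libraries. Every comparison therefore sets strains side by side that differ in markers as well as in the ts allele, and counts are given with and without the library labelled rpn5-ts replicate 1. URA3 and LEU2 are themselves genes of pyrimidine and leucine synthesis. Changes of those lists against WT therefore cannot be told apart from the marker differences. The same holds for arginine synthesis, as the arginine permease gene CAN1 differs from WT as well.

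**Figure D2:**
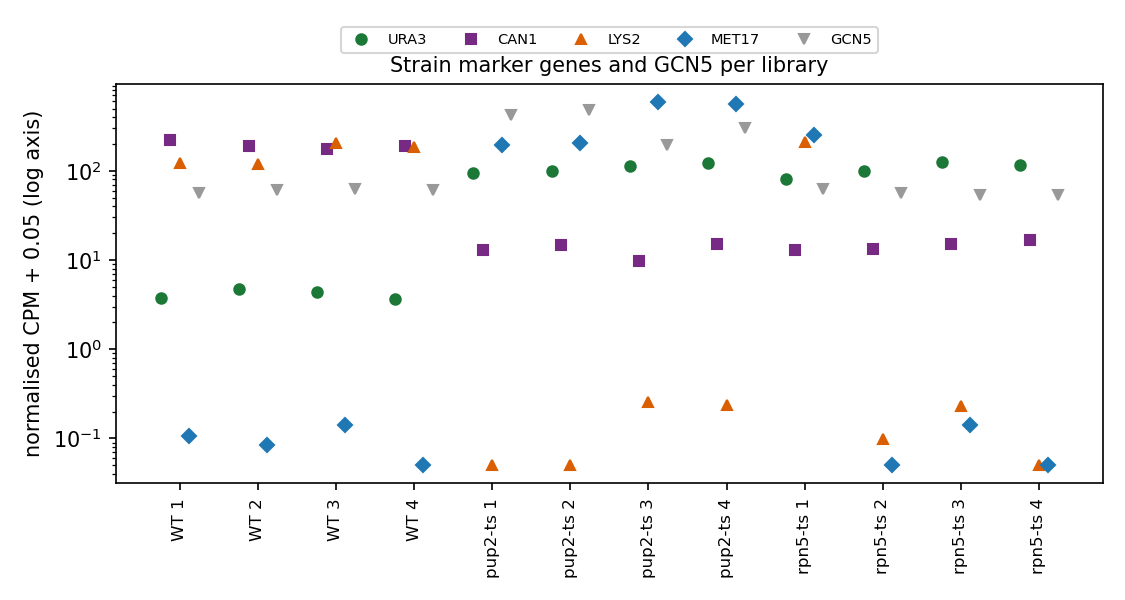
Normalised CPM (plus 0.05, log axis) of URA3, CAN1, LYS2, MET17 and GCN5 in each of the 12 libraries, one point per library. URA3 and CAN1 part WT from both mutants, LYS2 is near 0 in every mutant library except the one labelled rpn5-ts replicate 1 (213), MET17 is near 0 in WT and in rpn5-ts replicates 2 to 4, and GCN5 is 197 to 484 in pup2-ts alone.

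The comparison of pup2-ts with WT asks which transcripts change when a core-particle subunit carries a ts allele. Genes of the proteasome rose together: 13 of 14 core-particle genes and 19 of 19 regulatory-particle genes were higher, with median log2 fold changes of 1.20 and 1.16. Genes of iron uptake, of leucine and branched-chain amino acid synthesis and of a-cell mating were lower, though these 3 lists missed the threshold with an estimated correlation, and URA1 and URA4 of pyrimidine synthesis fell most among their list. The strains also differ by label in LEU2 and URA3, so the design does not separate the leucine and pyrimidine falls from these markers. Single genes with large changes included FIT1, whose product holds iron at the cell surface (63.1 ± 27.9 CPM in WT, 4.33 ± 1.40 in pup2-ts), and MAG1, a DNA repair glycosylase (17.0 ± 6.20 and 124 ± 30.6 CPM). In all, 855 of 5560 genes passed the edgeR quasi-likelihood test, 485 higher and 370 lower, and 174 differed beyond 1.5-fold (116 higher, 58 lower).

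With the replicate number as a block, 2142 genes passed (1084 higher, 1058 lower), among them 854 of the 855, and 261 differed beyond 1.5-fold. Replicates 1 and 2 alone gave 595 genes and replicates 3 and 4 alone 3651, with 76 and 715 beyond 1.5-fold. Replicates 3 and 4 lay closer together than 1 and 2 in every group. The chi-square of their counts per degree of freedom was 31.55 against 201.4 in WT, 9.224 against 17.94 in pup2-ts and 7.299 against 87.63 in rpn5-ts. In all comparisons, higher counts from replicates 3 and 4 alone thus rest on a small spread and do not by themselves show larger changes. Without pup2-ts replicate 3 the count was 528, with 115 beyond 1.5-fold, and without pup2-ts replicate 4 it was also 528. The fit without the library labelled rpn5-ts replicate 1 gave 872. All 4 libraries of one group lay beyond all 4 of the other for 1214 genes, 21.8%, against 2.86% by chance with exchangeable libraries. The 2.86% takes no account of the forms of name.

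Among core-particle genes, PRE1 rose from 187 ± 11.9 to 569 ± 27.5 CPM (log2 fold change 1.61 ± 0.10, adjusted p = 3.0e-06) and PRE3 from 147 ± 6.73 to 419 ± 41.7 CPM (1.51 ± 0.11, adjusted p = 4.5e-06). PUP2 itself, at 0.36 ± 0.12, missed the threshold (adjusted p = 0.058) and passed it with the block (adjusted p = 0.021), without pup2-ts replicate 1 (adjusted p = 0.045) and without the library labelled rpn5-ts replicate 1 (adjusted p = 0.044), in a range of 1.2e-05 to 0.28 over its alternatives. Adjusted over the list alone, 14 of 14 core-particle genes and 19 of 19 regulatory-particle genes were higher. Of the regulatory particle, the ATPase genes RPT6 (1.36 ± 0.08, adjusted p = 2.3e-06) and RPT1 (1.44 ± 0.10, adjusted p = 4.1e-06) had among the lowest p. RPN5 rose by 1.09 ± 0.22 (adjusted p = 0.0064). The list test gave adjusted p = 9.1e-41 for each particle, and adjusted p = 0.0098 (core) and 0.0057 (regulatory) with an estimated correlation. With the block and an estimated correlation together, chosen after the data were seen, each particle missed the threshold (adjusted p = 0.14), as did the assembly factors (0.15) and pyrimidine synthesis (0.15). Within replicates 1 and 2 the medians were 1.11 and 1.09, and within replicates 3 and 4 they were 1.32 and 1.26. RPN4, the transcription factor that drives proteasome genes and is itself a proteasome substrate, had -0.68 ± 0.41 (adjusted p = 0.32, or 0.047 with the block), and -0.098 when WT replicate 1 was left out (adjusted p = 0.89).

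Proteasome assembly and accessory factors rose in 8 of 16 cases (9 adjusted over the list alone), with a median of 0.55, adjusted p = 6.5e-09, and adjusted p = 0.011 with an estimated correlation. They included the chaperone gene UMP1 (1.34 ± 0.14, adjusted p = 6.2e-05) and the deubiquitinase gene UBP6 (1.07 ± 0.12, adjusted p = 1.1e-04). Genes of the ubiquitin pathway and of Cdc48, the ATPase that extracts ubiquitinated proteins, rose in 12 of 22 cases (13 higher and 1 lower adjusted over the list alone), with a median of 0.68, adjusted p = 3.0e-10, and adjusted p = 0.17 with an estimated correlation. DDI1 rose from 53.6 ± 10.4 to 224 ± 60.6 CPM (2.06 ± 0.20, adjusted p = 4.9e-05), NPL4 by 1.60 ± 0.11 (adjusted p = 4.1e-06) and CDC48 by 1.25 ± 0.12 (adjusted p = 2.9e-05). Medians within replicates 1 and 2, and within 3 and 4, were 0.47 and 0.59 for assembly factors and 0.44 and 0.79 for the ubiquitin pathway.

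Iron regulon genes fell in 10 of 19 cases (11 adjusted over the list alone), with a median of -0.81, adjusted p = 9.0e-09, and adjusted p = 0.14 with an estimated correlation. FIT2 and FIT3, cell-wall proteins that hold siderophore iron, and the putative reductase gene FRE5 are neighbours on chromosome XV (1059506 to 1063646), and FIT1 lies on chromosome IV (1503305 to 1504922). The siderophore transporter gene ARN2 had -1.86 ± 0.25 (adjusted p = 4.4e-04) and FIT2 had -2.32 ± 0.33 (adjusted p = 6.3e-04). Leucine and branched-chain synthesis genes fell in 7 of 10 cases (8 adjusted over the list alone), with a median of -0.72, adjusted p = 1.9e-07, and adjusted p = 0.16 with an estimated correlation. OAC1, a mitochondrial carrier, had -2.40 ± 0.37 (adjusted p = 0.0012) and the aminotransferase gene BAT1 had -1.82 ± 0.31 (adjusted p = 0.0022). Of 8 pyrimidine genes 2 fell, also adjusted over the list alone, URA1 and URA4, the latter from 505 ± 69.4 to 127 ± 3.60 CPM (-1.99 ± 0.11, adjusted p = 6.4e-07). That list had a median of -0.25, adjusted p = 3.8e-05, and adjusted p = 0.011 with an estimated correlation. Medians within replicates 1 and 2, and within 3 and 4, were -0.92 and -0.50 for iron, -0.40 and -1.03 for leucine, and -0.32 and -0.40 for pyrimidines.

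A-cell mating genes fell in 4 of 7 cases (6 adjusted over the list alone), with a median of -0.72, adjusted p = 9.4e-04, and adjusted p = 0.074 with an estimated correlation. MFA1, which encodes a-factor, had -1.11 ± 0.20 (adjusted p = 0.0038). Pheromone response genes fell in 4 of 14 cases (7 lower and 1 higher adjusted over the list alone), with a median of -0.49, adjusted p = 0.0052, and adjusted p = 0.059 with an estimated correlation. The cell-wall gene FIG2 had -0.99 ± 0.14 (adjusted p = 7.1e-04) and the sensor gene MSB2 had -1.30 ± 0.27 (adjusted p = 0.0080). Without WT replicates 3 or 4 or any 1 pup2-ts library, 2 mating genes were called. Medians within replicates 1 and 2, and within 3 and 4, were -0.64 and -0.80 for mating genes and -0.40 and -0.54 for the pheromone response.

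The list of ribosomal proteins was drawn by gene name and so also held RPP1, a subunit of RNase P. Of its 137 genes 1 was called, RPL9B, which was higher (0.64 ± 0.13, adjusted p = 0.0075) and shares 97 bases with YNL067W-B, and 0 were called adjusted over the list alone. The list passed with a median of -0.18 (adjusted p = 0.011) but had adjusted p = 0.88 with an estimated correlation, and its median was 0.050 within replicates 1 and 2 and -0.44 within 3 and 4. It missed the threshold without WT replicate 2 (adjusted p = 0.14), pup2-ts replicate 3 (0.15) or pup2-ts replicate 4 (0.076). Without WT replicate 1, RPL8B (-0.53, adjusted p = 0.035) and RPS15 (-0.43, adjusted p = 0.042) were called lower. With the block 1 gene of the list was called higher and 1 lower. Respiratory chain and ATP synthase genes fell in 4 of 31 cases (6 adjusted over the list alone). With the block 14 fell and 1 rose. The list had a median of -0.25, adjusted p = 0.015, and adjusted p = 0.72 with an estimated correlation. The medians were -0.11 and -0.44 within the forms, and the call was lost without WT replicate 4 (adjusted p = 0.059). None of 9 arginine genes was called, by edgeR or adjusted over the list alone, though the list passed with a median of 0.81 (adjusted p = 0.048, or 0.058 with the block, and 0.76 with an estimated correlation). With the block 4 of its genes were called higher. The mutants also differ from WT in CAN1, so the design does not separate the arginine values from that marker. Without the library labelled rpn5-ts replicate 1, ARG1 (adjusted p = 0.022), ARG56 (0.013) and ARG8 (0.0062) were called higher. The list's medians were 0.82 and 0.65 within the forms, and it missed the threshold without WT replicates 2, 3 or 4 (adjusted p = 0.065, 0.075 and 0.061) or pup2-ts replicates 1 or 2 (0.095 and 0.088).

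Outside the strain markers, the largest rise among genes that met the rule for naming was that of SNO1 of vitamin B6 synthesis (YMR095C, chromosome XIII, 457284 to 457958), at 1.58 ± 0.95 CPM in WT and 13 ± 6.02 in pup2-ts (3.03 ± 0.51, adjusted p = 0.0021). Its neighbour SNZ1 (458379 to 459451) rose by 2.49 ± 0.48 and FRM2, a nitroreductase gene, by 2.79 ± 0.40. GCN5 (YGR252W, chromosome VII, 996797 to 998387), the acetyltransferase of the SAGA complex, overlaps PUP2 from the other strand and rose from 60.3 ± 2.85 to 352 ± 128 CPM (2.55 ± 0.23, adjusted p = 2.9e-05). SDH9, the membrane-protein gene YRO2 and the transketolase gene TKL2 rose by 2.23 ± 0.46, 2.19 ± 0.41 and 2.17 ± 0.53, TKL2 with adjusted p = 0.017, or 0.051 without pup2-ts replicate 3. In replicates 1 and 2 alone, SNO1, SNZ1, SDH9 and TKL2 missed the threshold, at 1.88, 1.15, 1.62 and 1.41.

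Outside the strain markers, and among genes that met the rule for naming, the largest falls were FIT1 (-3.87 ± 0.38, adjusted p = 4.6e-05), the anaerobic cell-wall gene DAN1 (10.3 ± 2.20 to 0.774 ± 0.576 CPM, -3.73 ± 0.50), YMR317W (-3.44 ± 0.39), URA1 (-3.21 ± 0.30), FRE5 (-3.15 ± 0.50, or -2.35 without WT replicate 1), LEU1 (-3.10 ± 0.26), FIT3 (-2.83 ± 0.38) and NFG1 (-2.78 ± 0.38). URA1 encodes dihydroorotate dehydrogenase and fell from 2338 ± 403 to 253 ± 83.7 CPM (adjusted p = 3.8e-05). LEU1 encodes isopropylmalate isomerase and fell from 1126 ± 424 to 131 ± 15.8 CPM (adjusted p = 1.7e-05).

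The remaining 23 lists missed the threshold in pup2-ts. Among stress lists, medians were 0.15 for Hsf1-type chaperones, 0.058 for Msn2/4-type genes, 0.32 for Yap1-type genes, -0.10 for Pdr1/Pdr3-type genes (mean 0.20), 0.15 for the unfolded protein response, 0.075 for DNA damage and 0.27 for autophagy, with adjusted p from 0.0996 to 0.67. The Hsf1-type median was -0.43 within replicates 1 and 2 and 0.84 within 3 and 4. For growth and metabolism they were -0.017 for ribosome biogenesis, -0.0062 for translation factors (mean 0.0087), 0.35 for glycolysis, -4.6e-04 for the tricarboxylic acid cycle (mean 0.014), -0.33 for hexose transporters, -0.30 for lysine, -0.12 for histidine, -0.13 for sulfur amino acids, -0.10 for ergosterol and -0.43 for the phosphate regulon, with adjusted p from 0.061 to 0.96. For the cell cycle and surface they were -0.15 for histones, -0.39 for G1/S genes, -0.19 for G2/M genes, -0.25 for M/G1 genes, -0.46 for alpha-cell and diploid genes and -0.12 for cell wall integrity, with adjusted p from 0.13 to 0.51. Without WT replicate 1 the lists of Hsf1-type genes (adjusted p = 0.012), G1/S genes (0.045), autophagy (0.0099), ergosterol (0.017) and phosphate (0.026) passed, as did glycolysis without WT replicate 3 (0.019) and alpha-cell genes (0.047) and phosphate (0.021) without WT replicate 4. Phosphate also passed without pup2-ts replicate 1 (0.0034) or 2 (0.032), and autophagy without pup2-ts replicate 2 (0.034).

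The comparison of rpn5-ts with WT asks the same of a lid subunit of the regulatory particle. Here too genes of the proteasome rose, 14 of 14 for the core particle and 18 of 19 for the regulatory particle, with medians of 1.08 and 0.95. Iron uptake genes fell in 11 of 19 cases, and genes of leucine synthesis, of the pheromone response and of the transition from mitosis to G1 (M/G1) were lower as well, of which the leucine list missed the threshold with an estimated correlation. As in pup2-ts, the leucine fall is not separated from the LEU2 marker. FIT3 fell from 362 ± 129 to 30.2 ± 10.2 CPM and DAN1 from 10.3 ± 2.20 to 0.539 ± 0.236, and MAG1 rose from 17.0 ± 6.20 to 104 ± 11.6 CPM. The edgeR test called 760 of 5560 genes, 460 higher and 300 lower, of which 115 differed beyond 1.5-fold (72 higher, 43 lower).

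With the block, 2256 genes passed (1151 higher, 1105 lower), among them 759 of the 760, and 215 differed beyond 1.5-fold. Without the library labelled rpn5-ts replicate 1, whose markers differ from its label, 938 genes passed and 146 differed beyond 1.5-fold, and with the block as well these were 2306 and 267. Replicates 1 and 2 alone gave 698 genes, 73 beyond 1.5-fold, and replicates 3 and 4 alone 3531 and 630. The count was 489 without WT replicate 4 (72 beyond 1.5-fold), 475 without rpn5-ts replicate 2 (69), 446 without rpn5-ts replicate 3 (73) and 472 without rpn5-ts replicate 4 (74), and 75 differed beyond 1.5-fold without WT replicate 3. Non-overlapping groups were found for 1068 genes, 19.2%, against 2.86% by chance with exchangeable libraries.

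PRE1 rose from 187 ± 11.9 to 477 ± 47.8 CPM (1.35 ± 0.10, adjusted p = 1.6e-05) and PRE10 by 1.21 ± 0.09 (adjusted p = 1.9e-05). Among regulatory-particle genes, RPT6 rose by 1.16 ± 0.08 (adjusted p = 1.0e-05) and RPT1 by 1.28 ± 0.10 (adjusted p = 1.7e-05). PUP2 rose by 1.13 ± 0.12 (adjusted p = 1.3e-04). RPN5, the gene with the ts allele, had 0.56 ± 0.22 (adjusted p = 0.11, or 0.0033 with the block). It stood at 733 CPM in the library labelled rpn5-ts replicate 1 and at 400 to 514 in the other rpn5-ts libraries. Adjusted over the list alone, 14 of 14 and 19 of 19 genes were higher. The list tests gave adjusted p = 2.6e-36 (core) and 3.8e-30 (regulatory), and adjusted p = 0.0082 for each with an estimated correlation. With the block as well they missed the threshold (adjusted p = 0.11). Medians were 1.12 and 0.96 within replicates 1 and 2, and 1.04 and 0.96 within replicates 3 and 4. RPN4 had -0.58 ± 0.41 (adjusted p = 0.39), with 0.0075 in place of -0.58 when WT replicate 1 was left out.

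**Figure D3:**
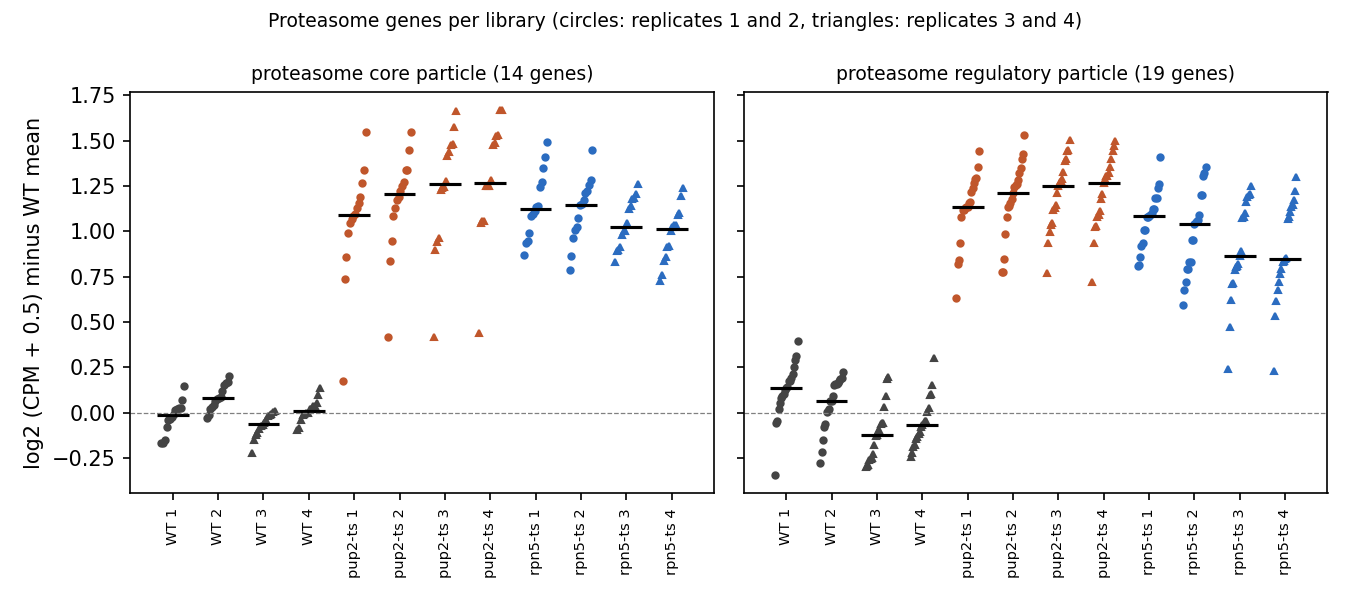
Log2 (CPM + 0.5) minus the WT mean for the 14 core-particle genes (left) and 19 regulatory-particle genes (right) in each library, one point per gene, with the median as a bar. Library medians lie between 1.09 and 1.27 (core) and 1.14 and 1.26 (regulatory) in pup2-ts, between 1.01 and 1.15 and 0.85 and 1.08 in rpn5-ts, and between -0.12 and 0.13 in WT.

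Assembly and accessory factors rose in 8 of 16 cases (12 adjusted over the list alone), with a median of 0.52, adjusted p = 2.0e-08, and adjusted p = 0.0099 with an estimated correlation. UBP6 rose by 0.98 ± 0.12 (adjusted p = 3.1e-04) and UMP1 by 1.08 ± 0.14 (adjusted p = 4.0e-04). Ubiquitin pathway and Cdc48 genes rose in 12 of 22 cases (13 higher and 2 lower adjusted over the list alone), with a median of 0.59, adjusted p = 1.2e-09, and adjusted p = 0.17 with an estimated correlation. DDI1 rose by 1.84 ± 0.20 (adjusted p = 1.5e-04), NPL4 by 1.41 ± 0.11 (adjusted p = 1.7e-05) and CDC48 from 847 ± 72.2 to 2017 ± 115 CPM (1.25 ± 0.12). Medians within replicates 1 and 2, and within 3 and 4, were 0.52 and 0.63 for assembly factors and 0.48 and 0.61 for the ubiquitin pathway.

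Hsf1-type chaperone genes rose in 4 of 23 cases, and in 4 adjusted over the list alone. The list had a median of 0.67, adjusted p = 9.6e-04, and adjusted p = 0.66 with an estimated correlation. HCH1, a regulator of Hsp90, rose by 0.72 ± 0.12 (adjusted p = 0.0028) and shares 153 bases with POP3, and the Hsp90 cofactor gene CPR6 rose by 1.37 ± 0.26 (adjusted p = 0.0059). The chaperone median was -0.11 within replicates 1 and 2 and 1.37 within 3 and 4. Msn2/4-type stress genes rose in 5 of 28 cases (6 adjusted over the list alone), with a median of 0.42, adjusted p = 5.0e-04, and adjusted p = 0.55 with an estimated correlation. The glycogen-branching gene GLC3 rose from 21.5 ± 4.91 to 49.9 ± 6.63 CPM (1.22 ± 0.16, adjusted p = 4.9e-04) and SOL4 by 1.53 ± 0.27 (adjusted p = 0.0037). Autophagy genes rose in 2 of 19 cases, and in 2 adjusted over the list alone, with a median of 0.38, adjusted p = 0.0073, and adjusted p = 0.55 with an estimated correlation. Medians within the forms were 0.13 and 0.60 for stress genes and 0.22 and 0.43 for autophagy. With the block 10 chaperone, 10 stress and 8 autophagy genes were called higher. Counts of genes called in these lists without the block depended on single libraries. For chaperones the count was 10 without WT replicate 1, 7 without the library labelled rpn5-ts replicate 1 and 2 without rpn5-ts replicates 3 or 4. For stress genes it was 8 without WT replicate 1 and 3 without WT replicates 2 or 4 or rpn5-ts replicates 3 or 4. For autophagy it was 5 without WT replicate 1, 4 without the library labelled rpn5-ts replicate 1 and 0 without any other 1 library of WT or rpn5-ts, where ATG1 and ATG3 missed the threshold (adjusted p = 0.051 to 0.12).

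Of the iron regulon, 15 of 19 genes fell adjusted over the list alone, with a median of -0.91, adjusted p = 3.8e-14, and adjusted p = 0.042 with an estimated correlation. ARN2 fell from 267 ± 110 to 51.0 ± 12.3 CPM (-2.38 ± 0.25, adjusted p = 1.3e-04). Leucine and branched-chain synthesis genes fell in 6 of 10 cases (8 adjusted over the list alone), with a median of -0.82, adjusted p = 2.5e-08, and adjusted p = 0.0997 with an estimated correlation, led by OAC1 (-2.59 ± 0.38) and BAT1 (-1.72 ± 0.31). Of 8 pyrimidine genes 2 fell, URA1 and URA4 (3 adjusted over the list alone), with a median of -0.32, adjusted p = 4.6e-06, and adjusted p = 0.0082 with an estimated correlation. URA4 had -1.97 ± 0.11 (adjusted p = 7.1e-07). In the phosphate regulon 4 of 15 genes fell and 1 rose (7 and 1 adjusted over the list alone), with a median of -0.61, adjusted p = 0.0034, and adjusted p = 0.55 with an estimated correlation. PHO5, the secreted acid phosphatase, had -1.37 ± 0.22 (adjusted p = 0.0019). Of phosphate genes 2 were called lower without WT replicate 2 and 1 without WT replicate 3 or rpn5-ts replicates 2, 3 or 4, and 0 higher without WT replicates 2 or 4 or rpn5-ts replicates 2, 3 or 4. Medians within replicates 1 and 2, and within 3 and 4, were -1.13 and -0.61 for iron, -0.46 and -1.19 for leucine, -0.33 and -0.47 for pyrimidines and -0.43 and -0.87 for phosphate.

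M/G1 genes fell in 7 of 15 cases, and in 7 adjusted over the list alone, with a median of -0.59, adjusted p = 5.0e-04, and adjusted p = 0.018 with an estimated correlation. They included the daughter-cell separation genes SCW11 (-0.88 ± 0.18, adjusted p = 0.0079), DSE2 (957 ± 115 to 404 ± 195 CPM, -1.24 ± 0.27, adjusted p = 0.010) and CTS1 (-1.20 ± 0.25, adjusted p = 0.0090), of which CTS1 shares 64 bases with YLR285C-A. Pheromone response genes fell in 7 of 14 cases (8 adjusted over the list alone), with a median of -0.61, adjusted p = 4.4e-04, and adjusted p = 0.018 with an estimated correlation. FAR1, which arrests the cell cycle in pheromone, had -0.79 ± 0.15 (adjusted p = 0.0066) and PRM5 had -1.0 ± 0.20 (adjusted p = 0.0074). A-cell mating genes fell in 3 of 7 cases (5 adjusted over the list alone), with a median of -0.61, adjusted p = 4.4e-04, and adjusted p = 0.057 with an estimated correlation. MFA1 fell from 98.0 ± 18.3 to 31.3 ± 5.31 CPM (-1.65 ± 0.21, adjusted p = 4.1e-04). Without WT replicate 2 or rpn5-ts replicates 2 or 4, 1 mating gene was called, and 4 pheromone response genes without WT replicate 4 or rpn5-ts replicate 2. Medians within the forms were -0.49 and -0.64 for M/G1, -0.59 and -0.48 for the pheromone response and -0.85 and -0.52 for mating genes. With the block and an estimated correlation together, M/G1 genes (adjusted p = 0.13) and the pheromone response (0.11) missed the threshold, as did every other list in rpn5-ts.

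Of the 137 genes of the ribosomal protein list 1 was called, RPL9B, which was higher, and 0 adjusted over the list alone, while the list had a median of -0.27, adjusted p = 3.8e-06, and adjusted p = 0.78 with an estimated correlation. RPL9B missed the threshold without any 1 library of WT or rpn5-ts except WT replicate 2 (adjusted p = 0.054 to 0.11). With the block 9 genes of the list were called lower and 1 higher. Without the library labelled rpn5-ts replicate 1, RPL22A (adjusted p = 0.025), RPL22B (0.022) and RPL8B (0.037) were called lower. So were RPL22A (0.047) and RPL8B (0.022) without WT replicate 1. The list's median was -0.056 within replicates 1 and 2 and -0.52 within 3 and 4. Ribosome biogenesis genes fell in 2 of 33 cases (0 adjusted over the list alone, 15 with the block). The list had a median of -0.20, adjusted p = 0.012, and adjusted p = 0.74 with an estimated correlation. The medians were -0.15 and -0.25 within the forms, and the list missed the threshold without rpn5-ts replicate 3 (adjusted p = 0.068). Of its genes 1 was called without WT replicates 1 or 4 or rpn5-ts replicate 2, and 0 without WT replicate 3 or rpn5-ts replicates 3 or 4.

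By the same rule, which leaves out strain markers, the largest rises were SDH9 (2.21 ± 0.24 to 15.0 ± 7.51 CPM, 2.76 ± 0.47, adjusted p = 0.0028), MAG1 (2.60 ± 0.25, adjusted p = 7.6e-05), the cardiolipin phospholipase gene CLD1 (2.25 ± 0.33), YRO2 (2.24 ± 0.41), BNA2 of NAD synthesis (2.10 ± 0.42), YPL113C (2.06 ± 0.33), YHR138C (1.97 ± 0.26) and TVS1 (1.94 ± 0.57). BNA2 shares 241 bases with YJR079W. TVS1 had adjusted p = 0.044 and missed the threshold without any 1 of WT replicates 1 to 4 or rpn5-ts replicates 3 and 4 (adjusted p = 0.075 to 0.13). In replicates 1 and 2 alone SDH9, CLD1 and BNA2 also missed it, at 2.27, 1.81 and 1.35. The largest falls by that rule were DAN1 (-4.29 ± 0.52, adjusted p = 3.3e-04), YMR317W (-3.83 ± 0.40), FRE5 (-3.68 ± 0.51, or -2.89 without WT replicate 1), FIT3 (-3.58 ± 0.39), FIT1 (-3.54 ± 0.37), URA1 (-3.25 ± 0.30), FIT2 (-3.06 ± 0.34) and LEU1 (-3.02 ± 0.25, adjusted p = 3.1e-05).

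The other 19 lists missed the threshold in rpn5-ts. Medians were 0.21 for Yap1-type genes, 0.15 for Pdr1/Pdr3-type genes, 0.20 for the unfolded protein response and 0.050 for DNA damage, with adjusted p from 0.066 to 0.61. For growth and metabolism they were -0.14 for translation factors, 0.30 for glycolysis, 0.39 for the tricarboxylic acid cycle, 0.019 for the respiratory chain, -0.35 for hexose transporters, -0.067 for lysine (mean 0.077), -0.23 for histidine, 0.64 for arginine, -0.095 for sulfur amino acids and -0.059 for ergosterol, with adjusted p from 0.17 to 0.98. Histones, G1/S, G2/M, alpha-cell and cell wall genes had -0.26, -0.30, 0.051, -0.22 (mean 0.12) and -0.27, with adjusted p from 0.21 to 0.83. With the block, the unfolded protein response (adjusted p = 0.017), glycolysis (0.042) and the tricarboxylic acid cycle (0.0087) passed, but missed the threshold with an estimated correlation as well (adjusted p = 0.23, 0.87 and 0.25). Without WT replicate 1, translation factors (0.021), ergosterol (0.041) and histones (0.019) passed, and without WT replicate 2 so did cell wall genes (0.034) and the unfolded protein response (0.030). Glycolysis passed without WT replicate 3 (0.016) or rpn5-ts replicate 2 (0.044), and the tricarboxylic acid cycle without WT replicate 3 (0.032), rpn5-ts replicate 2 (0.029) or the library labelled rpn5-ts replicate 1 (0.029). Histidine (0.0063) and histones (0.045) also passed without that library, and arginine without rpn5-ts replicate 3 (0.018) or 4 (0.0496). Arginine medians were 1.01 within replicates 1 and 2 and -0.060 within 3 and 4, and 0.018 without the library labelled rpn5-ts replicate 1.

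The mutants were also compared directly, which asks whether a core-particle and a lid allele differ, in strains that also differ in MET17 transcripts. MET17 had -2.63 (adjusted p = 0.98), and -13.4 (adjusted p = 6.5e-05) without the library labelled rpn5-ts replicate 1. Of the genes called, GCN5 had the largest difference, at 352 ± 128 CPM in pup2-ts and 56.4 ± 3.92 in rpn5-ts (rpn5-ts against pup2-ts -2.64 ± 0.23, adjusted p = 6.8e-04). GCN5 overlaps the altered PUP2 locus, so a local effect of that alteration cannot be told apart from a response to the allele. YHL050C (chromosome VIII, 368 to 3350), an open reading frame of a subtelomeric family whose near-identical copies share reads, was higher in rpn5-ts, at 29.6 ± 6.79 against 10.9 ± 1.01 CPM (1.44 ± 0.16, adjusted p = 0.0050). PUP2 had 0.76 ± 0.12, which missed the threshold (adjusted p = 0.051) and passed with the block (0.040) and without the library labelled rpn5-ts replicate 1 (0.027), in a range of 7.5e-07 to 0.41 over its alternatives. GCN5 and YHL050C were all that edgeR called of 5560, 1 of them beyond 1.5-fold, while 335 had an unadjusted p under 0.05 and DESeq2 called 27.

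The block called 7 genes, 4 higher and 3 lower. Without the library labelled rpn5-ts replicate 1, 46 were called (30 higher, 16 lower) and 10 beyond 1.5-fold, and with the block as well 371. Replicates 1 and 2 alone gave 1 gene and replicates 3 and 4 alone 1896, and YHL050C was not called with replicates 1 and 2 alone or with only the 8 libraries compared. Non-overlapping groups were found for 258 genes, 4.6%, against 2.86% by chance with exchangeable libraries, which the forms of name make doubtful.

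M/G1 genes were lower in rpn5-ts than in pup2-ts, with a median of -0.24, adjusted p = 2.0e-05, and adjusted p = 0.027 with an estimated correlation, although 0 of 15 were called by edgeR over all genes and 2 adjusted over the list alone, both lower. With the block the M/G1 median was -0.13 (adjusted p = 4.9e-06) with 0 genes called, and with an estimated correlation as well the list missed the threshold (adjusted p = 0.20). Its median was -0.13 within replicates 1 and 2 and -0.38 within 3 and 4. Core-particle genes had a median of -0.17 (adjusted p = 0.0046) and regulatory-particle genes of -0.19 (adjusted p = 8.3e-08), with 0 of 14 and 0 of 19 called, and 1 higher and 0 adjusted over the list alone. With an estimated correlation both missed the threshold (adjusted p = 0.64 and 0.35), and the core particle also missed it without pup2-ts replicate 4 (0.084) or rpn5-ts replicate 4 (0.062). Within replicates 1 and 2 the core particle had -0.017 (adjusted p = 0.63) and the regulatory particle -0.089, and within 3 and 4 they had -0.275 and -0.29. The lowest p belonged to lists that were higher in rpn5-ts, respiratory chain genes (0.27, adjusted p = 3.2e-11) and Msn2/4-type stress genes (0.48, adjusted p = 7.3e-11), and Hsf1-type chaperones were higher as well (0.47, adjusted p = 1.1e-05). Of these lists 0 genes were called, and with an estimated correlation they missed the threshold (adjusted p = 0.35, 0.40 and 0.60). In all 15 of 35 lists passed, 7 higher and 8 lower in rpn5-ts, and 1 with an estimated correlation.

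Changes against WT ran together in the mutants across genes. Over 5555 genes outside the markers, Pearson's r of the log2 fold changes was 0.871 and Spearman's rho 0.845, and 84.4% of genes had the same sign. These are values across genes, which are not independent replicates, and both comparisons share the WT libraries. In 20 simulated pairs of unchanged groups, set against simulated WT libraries shared by both, r averaged 0.498 (0.456 to 0.531). The same sign was found for 66.7% of simulated genes and at most 0 calls were shared. Simulated genes varied independently, without the forms of name or the markers in which both mutants differ from WT. The higher real r is therefore not ascribed to the ts alleles alone. Both mutants had 342 genes called higher and 202 called lower, where independent lists of that length would share 39.7 and 19.8, and 0 genes were called in opposite directions. With the 4 WT libraries split between the comparisons in 6 ways, r ranged from 0.407 to 0.821, and 71 to 186 calls were shared where independent lists would share 1.8 to 18.6. The 2 splits that gave 1 mutant WT replicates 1 and 2 and the other WT replicates 3 and 4 had 0.407 and 0.409, and the 4 balanced for the form of name had 0.732 to 0.821. Without pup2-ts replicate 3 or 4, or the library labelled rpn5-ts replicate 1, r was 0.842, 0.840 and 0.814.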

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

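Tests on a few abundant genes, on WT cells or a pup2-ts library for the library labelled rpn5-ts replicate 1, and on the non-coding units were chosen after the result was seen; those on depth, length and GC content, RPN5 and the splits were chosen before.

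Replicates 1 and 2 and replicates 3 and 4 differed in 3511 genes, among them all 16 glycolysis genes. With all libraries thinned to the depth of the shallowest, 97.4% of these genes were still called, which argues against depth. With the 100 most abundant genes removed and no TMM factors, 92.4% of the called genes outside those 100 were still called, which argues against a few genes taking most of the counts. With the trend on gene length and GC content removed, 71.1% were still called, which leaves that trend open as a part. No group of the design gives a biological explanation, and a difference in culture or library batch may lie behind it but was not tested.

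The library labelled rpn5-ts replicate 1 had 212.6 CPM of LYS2 (other rpn5-ts libraries 0 to 0.181) and 249.4 CPM of MET17 (others 0 to 0.0906), each far from the other replicates. CAN1 stood at 6.59% of the WT mean and LYS2 at 134.1%, which argues against WT cells mixed in, and 212.6 CPM of LYS2 against at most 0.209 in pup2-ts argues against a pup2-ts library. RPN5 relative to the other regulatory-particle genes was 0.562 on the log2 scale, within the 0.28 to 0.78 of WT and pup2-ts. It was above the mean of -0.049 (SD 0.12) in the other rpn5-ts libraries. This measure also followed the form of name. In WT and pup2-ts it was 0.579 to 0.782 in replicates 1 and 2 and 0.28 to 0.391 in replicates 3 and 4. Among libraries of its own form, 0.562 thus lay just below WT and pup2-ts and above the 0.0901 of rpn5-ts replicate 2. A candidate explanation is another strain of the same marker cassette with an unmodified RPN5 locus, which counts per gene do not prove. Proteasome genes were raised in this library all the same, with medians of 1.12 (core) and 1.08 (regulatory). The other rpn5-ts libraries had 1.01 to 1.15 and 0.85 to 1.04. It correlated at 0.991 with pup2-ts replicate 1 and 0.978 with rpn5-ts replicate 2. Its proteasome rise therefore cannot be ascribed to an RPN5 allele. The pup2-ts libraries also held MET17 transcripts that their labels exclude, so a cross that kept MET17 stays open and untested.

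Non-coding units, which no comparison of genes uses, were mostly lower in the mutants: 1327 lower and 149 higher of 4666 in pup2-ts (median -0.53, or -0.518 and -0.470 within replicates 1 and 2 and within 3 and 4, 2204 called with the block), and 579 lower and 176 higher in rpn5-ts (median -0.30, or -0.419 and -0.114, 1485 with the block). Units clear of genes on both strands had a median of -0.537 in pup2-ts, against -0.531 opposite a gene, which argues against leakage from the other strand. In the middle range of read density of the clear units, 320 genes had medians of -0.270 in pup2-ts and -0.017 in rpn5-ts. The 392 of 784 clear units in that range had -0.522 and -0.349. The genes were higher by 0.252 (0.151 to 0.359) and 0.332 (0.249 to 0.434). As neither lower end passed the bound set for the test, background reads stay open as a part. Between libraries of 1 form, the highest median difference was -0.376 in pup2-ts, so the difference between the forms is not its cause, and -0.087 in rpn5-ts, which did not pass the bound set for the test. Each group holds 2 libraries of each form, so in rpn5-ts only an effect of the form that differs from that in WT stays open, beside the ts alleles and marker genes, which the design does not separate in either mutant.

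Of 93 groups of 4 values, 9 held a library far from the other 3, where chance gives 1 in 20, or 4.7, and 3 of these were in WT replicate 1, 2 in pup2-ts replicate 1, 3 in the library labelled rpn5-ts replicate 1 and 1 in rpn5-ts replicate 2. In WT replicate 1, SNO1 stood at 2.998 CPM (others 0.978 to 1.26), FRE5 at 45.62 (10.2 to 13.4) and GCN5 at 56.06 (61.4 to 62.3). In pup2-ts replicate 1, PUP2 stood at 219.9 CPM (others 260 to 264) and FIT2 at 50.78 (45.8 to 46.1). YMR317W stood at 7.275 CPM in the library labelled rpn5-ts replicate 1 (others 3.69 to 4.26), and HIS3 at 67.4 in rpn5-ts replicate 2 (103 to 105). The mutants differed by -2.64 for GCN5 and 1.44 for YHL050C, each by the test of the difference itself, and the M/G1 list differed by -0.2414.

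Other splits of the 8 libraries of a comparison into 4 and 4 were fitted, 35 in each, the real one included. For pup2-ts against WT, 2 of 35 gave as many genes as the real 855, the other being the split by form of name (1607), so chance is not excluded by that count. Beyond 1.5-fold 1 of 35 gave as many (174, highest other 0), and for the median of the proteasome genes 1 of 35 was as large (1.19, highest other 0.668). These 35 take no account of the replicate numbers, which may pair the libraries, and only 8 of them part every pair, too few for a share under 0.05. For rpn5-ts against WT the counts of such splits were 2 (760, the split by form gave 1175), 1 (115, highest other 0) and 1 (0.967, highest other 0.588). Between the mutants 2 splits gave as many genes (2) and 2 as many beyond 1.5-fold (1, highest other 138), so chance is not excluded. For lists called it is not excluded either, with 23 splits as high in pup2-ts against WT (12, highest other 20), 14 in rpn5-ts against WT (16, highest other 25) and 12 between the mutants (15, highest other 19). The split by form called far more genes between the mutants than the real one, 2757 against 2, which points to a structure of the libraries. With the block those 8 splits are again too few, and the real split was the 1 with as many in each, at 2142 (highest other 0), 2256 (389) and 7 (0).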

How the results depend on the processing

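The alternatives that left out the library labelled rpn5-ts replicate 1 from pup2-ts against WT, joined the block with a left-out library or with an estimated correlation, or took all annotated features were chosen after the data were seen, as were the block and left-out libraries for Pearson's r. Over all alternatives, tests of lists and log2 fold changes of named genes kept direction and side of the threshold in 1429 and 3229 cases. They lost the call in 75 and 181, gained one in 72 and 172 and turned in 65 and 17. Counts of genes stayed within 1.5 times in 75 cases and moved further in 59, and counts of lists in 60 and 7. On simulated data 22% of genes changed by 1.5-fold were recovered, so at this spread small changes are missed. All annotated features moved the median of all genes by 0.15 in pup2-ts against WT and 0.091 in rpn5-ts. Apart from the alternatives that use fewer libraries, for which fewer libraries also mean less power, the cause was not tested. Lists said to have turned below are those whose test changed direction, whatever the sign of the median, and they are given with the median.

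With upper-quartile factors, genes called beyond 1.5-fold numbered 2 in rpn5-ts against pup2-ts. Tricarboxylic acid cycle (-0.024) turned in pup2-ts against WT. URA3 had 0.025 in rpn5-ts against pup2-ts. With DESeq2, genes called numbered 27 in rpn5-ts against pup2-ts and genes called beyond 1.5-fold numbered 2 in rpn5-ts against pup2-ts. With limma-voom, genes called beyond 1.5-fold numbered 112 in pup2-ts against WT and 60 in rpn5-ts against WT. With a filter at 10 CPM, genes called numbered 4 in rpn5-ts against pup2-ts. Translation factors (-0.019) turned in pup2-ts against WT. With the replicate number as a block, genes called numbered 2142 in pup2-ts against WT, 2256 in rpn5-ts against WT and 7 in rpn5-ts against pup2-ts and genes called beyond 1.5-fold numbered 215 in rpn5-ts against WT. Tricarboxylic acid cycle (0.030) turned in pup2-ts against WT. With the form of the name as a factor, genes called numbered 2371 in pup2-ts against WT, 2474 in rpn5-ts against WT and 32 in rpn5-ts against pup2-ts and genes called beyond 1.5-fold numbered 274 in pup2-ts against WT, 233 in rpn5-ts against WT and 2 in rpn5-ts against pup2-ts. Tricarboxylic acid cycle (0.030) turned in pup2-ts against WT. With replicates 1 and 2 alone, genes called numbered 1 in rpn5-ts against pup2-ts and genes called beyond 1.5-fold numbered 76 in pup2-ts against WT and 73 in rpn5-ts against WT. Hsf1-type chaperones (-0.42), Pdr1/Pdr3-type genes (-0.19), ergosterol (0.080), histidine (0.0082), histones (0.095), ribosomal proteins (0.055), ribosome biogenesis (0.071) and tricarboxylic acid cycle (0.040) turned in pup2-ts against WT. G1/S genes (-0.039), G2/M genes (-0.10), Pdr1/Pdr3-type genes (-0.017), histidine (0.012), histones (0.12), lysine (0.19) and translation factors (-0.020) turned in rpn5-ts against WT. Proteasome core particle (-0.017) turned in rpn5-ts against pup2-ts. CAN1 had -0.075 in rpn5-ts against pup2-ts. With replicates 3 and 4 alone, genes called numbered 3651 in pup2-ts against WT, 3531 in rpn5-ts against WT and 1896 in rpn5-ts against pup2-ts; genes called beyond 1.5-fold numbered 715 in pup2-ts against WT, 630 in rpn5-ts against WT and 103 in rpn5-ts against pup2-ts; lists called numbered 20 in pup2-ts against WT. Sulfur amino acids (0.15), translation factors (-0.13) and tricarboxylic acid cycle (0.035) turned in pup2-ts against WT. Alpha-cell genes (0.047) and arginine (-0.057) turned in rpn5-ts against WT. LYS2 had -0.99 and URA3 had 0.040 in rpn5-ts against pup2-ts. With only the 8 libraries compared, genes called numbered 1 in rpn5-ts against pup2-ts and genes called beyond 1.5-fold numbered 0 in rpn5-ts against pup2-ts. With an estimated correlation, lists called numbered 4 in pup2-ts against WT, 7 in rpn5-ts against WT and 1 in rpn5-ts against pup2-ts. With the block and an estimated correlation, lists called numbered 0 in pup2-ts against WT, 0 in rpn5-ts against WT and 0 in rpn5-ts against pup2-ts. Proteasome core particle had 1.21 (adjusted p = 0.14) and proteasome regulatory particle had 1.17 (adjusted p = 0.14) in pup2-ts against WT. Tricarboxylic acid cycle (0.030) turned in pup2-ts against WT. Proteasome core particle had 1.08 (adjusted p = 0.11) and proteasome regulatory particle had 0.95 (adjusted p = 0.11) in rpn5-ts against WT. With the block and without WT replicate 1, genes called numbered 2730 in pup2-ts against WT, 2927 in rpn5-ts against WT and 276 in rpn5-ts against pup2-ts and genes called beyond 1.5-fold numbered 368 in pup2-ts against WT, 381 in rpn5-ts against WT and 0 in rpn5-ts against pup2-ts. Translation factors (-0.031) and tricarboxylic acid cycle (0.081) turned in pup2-ts against WT. Alpha-cell genes (-0.14) turned in rpn5-ts against WT. With the block and without the library labelled rpn5-ts replicate 1, genes called numbered 2297 in pup2-ts against WT, 2306 in rpn5-ts against WT and 371 in rpn5-ts against pup2-ts and genes called beyond 1.5-fold numbered 281 in pup2-ts against WT, 267 in rpn5-ts against WT and 14 in rpn5-ts against pup2-ts. Tricarboxylic acid cycle (0.033) turned in pup2-ts against WT. Alpha-cell genes (-0.12) turned in rpn5-ts against WT. MET17 had -0.32 in rpn5-ts against WT. LYS2 had -0.35 and URA3 had 0.032 in rpn5-ts against pup2-ts. With all annotated features in place of protein-coding genes, genes called numbered 2432 in pup2-ts against WT, 1709 in rpn5-ts against WT and 4 in rpn5-ts against pup2-ts and genes called beyond 1.5-fold numbered 495 in pup2-ts against WT, 238 in rpn5-ts against WT and 3 in rpn5-ts against pup2-ts. Ergosterol (0.032), histidine (0.025), histones (-0.015), ribosome biogenesis (0.14), sulfur amino acids (0.029) and tricarboxylic acid cycle (0.14) turned in pup2-ts against WT. G1/S genes (-0.20), alpha-cell genes (-0.13) and lysine (0.026) turned in rpn5-ts against WT.

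Leaving out 1 library at a time, counts of genes called ranged over 528 to 872 (pup2-ts against WT), 115 to 177 (beyond 1.5-fold, pup2-ts against WT), 446 to 938 (rpn5-ts against WT), 69 to 146 (beyond 1.5-fold, rpn5-ts against WT), 2 to 46 (rpn5-ts against pup2-ts) and 1 to 10 (beyond 1.5-fold, rpn5-ts against pup2-ts). For some lists the test turned with a library left out. In pup2-ts against WT their medians ranged over Msn2/4-type genes -0.095 to 0.19, ribosome biogenesis -0.071 to 0.070 and translation factors -0.041 to 0.060. Those of the tricarboxylic acid cycle ranged over -0.14 to 0.17 and of sulfur amino acids over -0.23 to -0.036. In rpn5-ts against WT the medians of such lists ranged over glycolysis 0.0056 to 0.71, respiratory chain -0.040 to 0.097 and lysine -0.35 to 0.034. Those of arginine ranged over 0.018 to 0.81, of G2/M genes over -0.010 to 0.14 and of alpha-cell genes over -0.29 to -0.13. Log2 fold changes of single genes that turned ranged over RPN4 -0.80 to 0.0075 (rpn5-ts against WT), MET17 -0.15 to 11.04 (rpn5-ts against WT), LYS2 -0.24 to 9.86 (rpn5-ts against pup2-ts), RPN4 -0.10 to 0.24 (rpn5-ts against pup2-ts), URA3 -0.11 to 0.084 (rpn5-ts against pup2-ts) and HIS3 -0.15 to 0.037 (rpn5-ts against pup2-ts). Pearson's r between the mutants ranged from 0.814 to 0.880, and from 0.407 to 0.821 with the WT libraries split.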

Other observations

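Tests of how the mutants differed from WT within each form of name were chosen after the forms were seen. Chaperone genes of the Hsf1 type followed the form. In rpn5-ts 16 of 23 were called higher in replicates 3 and 4 and 6 in replicates 1 and 2, with medians of 1.37 and -0.11. In pup2-ts 11 of 23 were called higher in replicates 3 and 4, and 2 higher and 3 lower in replicates 1 and 2, with medians of 0.84 and -0.43. The difference between forms had adjusted p = 3.8e-14 in rpn5-ts and 4.9e-10 in pup2-ts, but adjusted p = 0.55 and 0.59 with an estimated correlation.

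Histone genes showed the opposite: 7 of 9 were called lower in replicates 3 and 4 in rpn5-ts (median -0.66) and 6 of 9 in pup2-ts (-0.53), against 0 lower in replicates 1 and 2 (0.10 and 0.090). The difference had adjusted p = 2.2e-08 and 1.9e-04, and adjusted p = 0.55 and 0.62 with an estimated correlation. G1/S genes had medians of -0.099 and -0.68 in pup2-ts, with 12 of 17 called lower and 3 higher in replicates 3 and 4, and 1 lower and 3 higher in replicates 1 and 2 (adjusted p = 5.3e-07, and adjusted p = 0.19 with an estimated correlation). Single genes differed between the forms in 523 cases in pup2-ts (330 larger and 193 smaller in replicates 3 and 4) and in 93 in rpn5-ts (69 and 24).

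GCN5 and PUP2 lie on opposite strands and overlap on chromosome VII. An antisense unit within GCN5 on the strand of PUP2 (AS_Unit3438, 997685 to 997985), named after its values were seen, stood at 5.58 CPM in WT, 0.078 in pup2-ts and 4.47 in rpn5-ts.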
